A study of Solanum lycopersicum with 21 samples.

How the data were processed

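Leaf RNA was measured in 21 libraries of the tomato cultivar M82 (Solanum lycopersicum). The libraries fall into 7 groups of 3 biological replicates. Per the labels each replicate held at least 3 fully expanded leaves, 1 per plant. The labels also name 5 plants, read here as the number per condition. If that reading holds, 5 plants are too few for 3 replicates of at least 3 plants each unless replicates shared plants. The libraries of a group would then not be independent, and the adjusted p given here would be too small. Otherwise the reading of 5 plants per condition is wrong. Which of these holds was not settled here, and the tests treat the libraries as independent. Wild-type plants and line 6936, in which the strigolactone synthesis gene CCD7 is silenced, were sampled in 3 conditions. These were irrigated plants, plants irrigated again after 1 drought, and plants irrigated again after 2 droughts. A further wild-type group was sprayed with the synthetic strigolactone analogue GR24 5DS at 5 µM, 24 h before sampling. Per the labels' protocols, line 6936 holds 70 to 80% less strigolactone in roots and root exudates. The value in leaves is not given in the sources used here. Groups were taken from the sample titles and treatment labels, and the replicate numbers from the titles.

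Per the labels' protocols, libraries were made from 1 µg of total RNA with a NEBNext Ultra RNA kit and sequenced as paired ends. That kit does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, HISAT2, a read aligner, and HTSeq, a read counter, were used. Their versions, their settings and the genome build are not given in the sources used here. The deposited table holds the authors' whole-number counts per gene, with no normalisation. It lists 35039 IDs, of which 33925 begin with Solyc, the tomato locus prefix, and 1114 begin with ENSRNA. Of all IDs, 9577 had no count in any of the 21 libraries. A further 6 columns of counts in the table match no sample in the labels and were not used. Counting of reads shared by near-identical genes is not described in the sources used here, so counts of close paralogs are uncertain.

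No genome was used here. The table of RefSeq genes used here, of assembly SLM_r2.1, holds 41476 genes, and 0 of the 35039 IDs matched an ID, locus tag or synonym in it. The files do not pair IDs with gene names. IDs are therefore printed as the table gives them, without symbols and without coordinates, and at most 2 higher and 2 lower IDs were taken per comparison. The chromosome of a Solyc ID is the number that follows the prefix in the ID itself.

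Total counts per library ranged from 19267602, in GR24 replicate 8, to 35433511, in GR24 replicate 11. A single library's floor, set at 3 counts, corresponded to between 0.0847 and 0.156 CPM (the usual unit of counts divided by library total). Intervals and floors cover counting error only, since PCR copies are not independent molecules. Replicates were compared before averaging with a chi-square statistic on genes with at least 20 counts per pair. The statistic per degree of freedom ranged from 28.9 to 334 over the 21 replicate pairs, where sampling noise alone gives about 1. No pair was treated as 1 library.

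Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr on the 7 groups, which left 20373 IDs. Library sizes were scaled by TMM factors. One quasi-likelihood fit (glmQLFit and glmQLFTest, both robust where offered) held 1 mean per group over all 21 libraries, with 14 residual degrees of freedom. It gave 10 comparisons of 2 groups and 2 interactions, which test whether the response to recovery differs between the genotypes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all IDs tested. Standard errors were computed from the log2 fold change and the F statistic. Levels are TMM-normalised CPM, as mean ± SD of 3 libraries unless stated. Principal components were computed on log2 CPM with a prior count of 2.

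The ID rule, fixed before the data were examined, took called genes with a mean log2 CPM of at least 1 and no overlap between the 3 libraries of each group, in order of fold change. It also asked for a gene name. Since no ID had one, that condition was dropped. For the interactions the called IDs of smallest p in each direction were taken, with the same minimum mean log2 CPM. A check of the silenced gene and tests of 22 gene lists had been fixed as well. They were not run, because the lists hold locus IDs written from memory and no source used here pairs those IDs with genes. A locus was called on in 1 genotype when every library of it reached 1 CPM and every library of the other lay at or below 0.1 times the lowest of those levels. This rule was set after the data were examined.

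Folds against a group with 0 counts are lower bounds computed against 3 counts over the whole group. Where a group had 1 to 3 counts, the ratio is given with its exact 95% binomial counting interval. Comparisons that share control libraries were set beside 20 simulations of unchanged groups. In these, all libraries, controls included, were drawn with the same mean per gene in every group. They hold the effect of sharing a noisy control group, but no real deviation of the control libraries used here. With 3 controls per group, the controls could not be divided into 2 sets of at least 2.

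The test was first run on simulated counts drawn from the means and library sizes of these samples. For recovery 1 against irrigated wild type, over 20099 genes, it recovered 28% of 100 genes changed 2-fold and 68% of 100 changed 4-fold, with 3 false calls. For the spray against irrigated wild type, over 20108 genes, it recovered 32% of 100 genes changed 2-fold and 63% of 100 changed 4-fold, with 6 false calls.

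The alternatives were the size factors of DESeq2, upper-quartile factors, the DESeq2 1.42.0 Wald test, no filter, a filter of 1 CPM in 3 libraries, and a fit of the compared groups alone. Others were a log2 fold change of at least 1, each library left out in turn, and the replicate number as a block, in edgeR and in limma 3.58.1. These were chosen before the data were examined. Alternatives for counts over several comparisons were added after seeing the data.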

Results

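Leaves of wild-type tomato and of a strigolactone-depleted line were sequenced to compare their transcripts under irrigation and after recovery from 1 or 2 droughts. Strigolactones are plant hormones made from carotenoids, and CCD7, which is silenced in the depleted line, is a carotenoid cleavage dioxygenase of their synthesis. There were 7 groups of 3 libraries. Irrigated plants carry the time label 0, recovery 1 the label 31 and recovery 2 the label 76, without a unit, and the sprayed plants, sampled 24 h after GR24, the label 24. Each recovery group therefore differs from its irrigated group in sampling time as well as in drought history. Per the labels' protocols the sprayed plants were sampled as the drought series began, yet their label differs from that of the irrigated wild type, so a difference in sampling time is not excluded there either. Total counts per library ranged from 19267602 to 35433511, and 20373 IDs entered the tests.

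The first principal component, with 36.4% of the variance, parted the unsprayed libraries by genotype. The 9 libraries of the depleted line lay between −90.9 and −11.1 on it. The 9 wild-type libraries without spray lay between 30.5 and 100.6. Of the sprayed wild-type libraries, replicate 8 lay inside that wild-type range at 43.8, replicate 9 inside the range of the depleted line at −25.1, and replicate 11 between the ranges at −2.9. The second component, with 12.4% of the variance, set the sprayed libraries, at −49.9 to −104.9, apart from the other 18. Irrigated wild-type libraries lay at its opposite end, at 35.5 to 54, and the next highest library stood at 30. In the depleted line, replicate 16 of recovery 1 stood apart at −11.1, while replicates 17 and 12 of that group lay at −90.9 and −69.7.

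**Figure D1:**
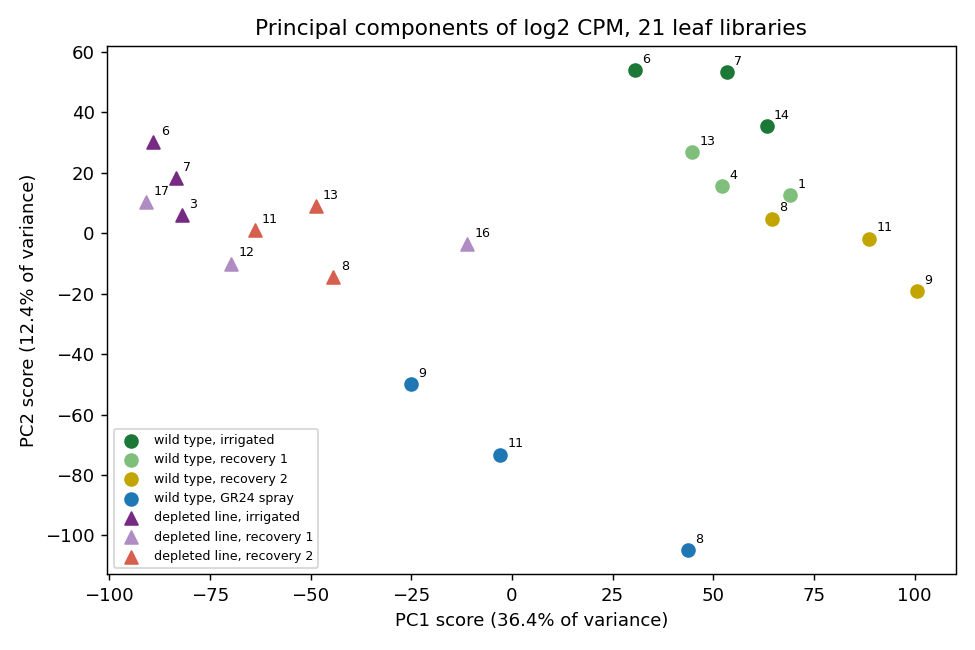
First and second principal component scores of log2 CPM for the 21 libraries, 1 point per library, coloured by group and marked with its replicate number (circles wild type, triangles depleted line). The axes hold 36.4% and 12.4% of the variance, and the 3 sprayed libraries lie below all others on the second.

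A few loci were read in 1 genotype and hardly or not at all in the other. Solyc01g090660.3 was read in all 9 libraries of the depleted line, at 85.0 to 305 CPM (193 ± 69.5, SD, n = 9), and had 0 counts in all 12 wild-type libraries, at least 25000-fold less. Solyc06g060640.1 was read at 108 to 264 CPM in the depleted line (191 ± 48.0, SD, n = 9) and with 11 counts in all over the 12 wild-type libraries. The ID next to it in number, Solyc06g060630.1, showed the same contrast at a lower level, 15.6 ± 3.30 CPM (SD, n = 9) against at most 0.432. The reverse held for Solyc07g052790.2, with 25.2 ± 8.46 CPM in the wild type (SD, n = 12) and 9 counts over the 9 depleted libraries. These 3 loci on in the depleted line and 1 on in the wild type were all that met the rule, and the same numbers met it without replicate 16. Since no source used here pairs IDs with genes, the level of CCD7 itself was not analysed here.

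**Figure D2:**
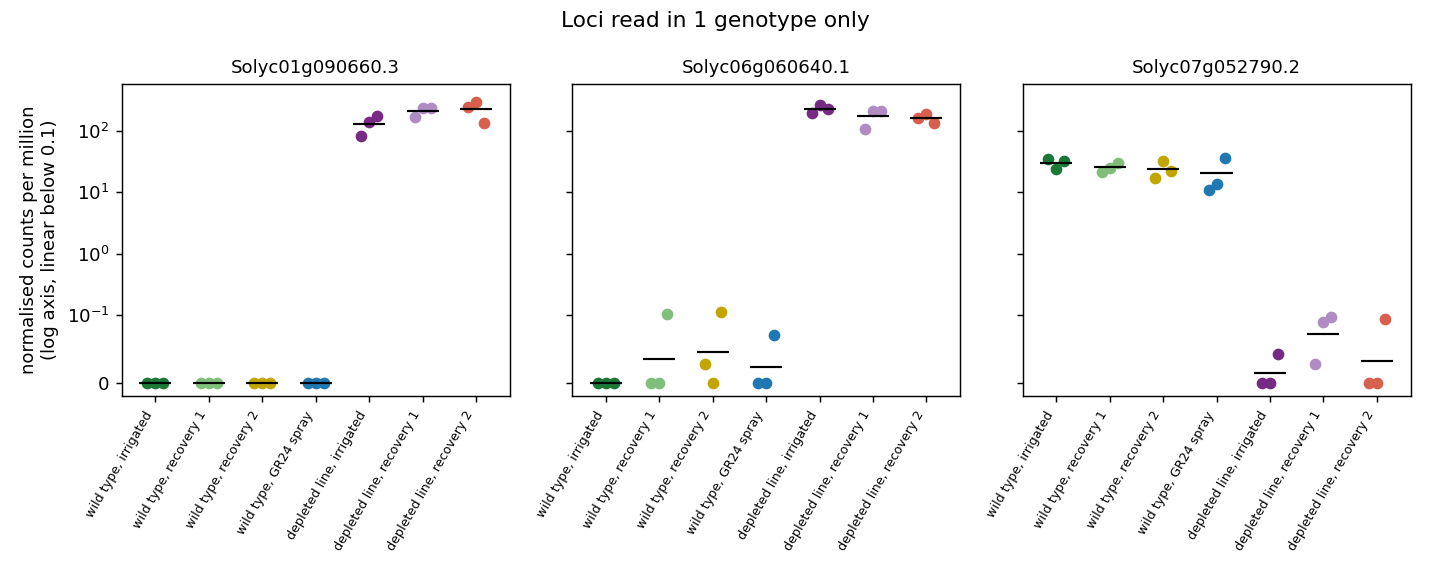
Normalised counts (CPM) of 3 loci in each of the 21 libraries, by group (points, 1 per library; bars, mean of 3 libraries), on an axis that is logarithmic above 0.1 CPM and linear below. Solyc01g090660.3 lies at 0 in the 12 wild-type libraries and at 85.0 CPM or more in the 9 depleted ones.

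Under irrigation, the depleted line differed from the wild type in 7001 of 20373 genes, 3751 higher and 3250 lower. The majority direction depended on the scaling, since upper-quartile factors gave 3293 higher and 3751 lower. The median size of the called changes was 1.05 on the log2 scale. Solyc06g060640.1 stood at 230 ± 32.9 CPM in the depleted line (SD, n = 3) against 0 counts, at least 6750-fold higher. Solyc07g052790.2 stood at 30.5 ± 5.58 CPM in the wild type (SD, n = 3) and had 1 count in the depleted line, a ratio of 2000 (95% interval 358 to 79000). Solyc01g103920.3 stood at 17.4 ± 6.60 CPM in the wild type and 0.0790 ± 0.0983 in the depleted line (SD, n = 3), a log2 fold change of −7.75 ± 1.51 (SE). In the depleted line, 4 of its 5 counts lay in replicate 3. Its edgeR adjusted p was 0.00107, and it was not called by limma (adjusted p = 0.0712). With a log2 fold change of at least 1, 3734 genes remained among the calls.

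After recovery from 1 drought, 3999 genes differed between the genotypes, 2020 higher and 1979 lower in the depleted line. Solyc01g090660.3 reached 216 ± 39.8 CPM there (SD, n = 3), at least 7020-fold above the 0 counts of the wild type. Solyc03g116970.2 was at 10.3 ± 5.29 CPM in the wild type and had 3 counts in the depleted line, a ratio of 312 (95% interval 107 to 1520). After 2 droughts, 5423 genes differed, 3040 higher and 2383 lower. Solyc07g052790.2 was then at 24.1 ± 7.94 CPM in the wild type (SD, n = 3) and had 2 counts in the depleted line, a ratio of 808 (95% interval 224 to 6680). Solyc01g008510.3 was at 0.359 ± 0.622 CPM in the depleted line against 201 ± 239 (SD, n = 3), a log2 fold change of −9.19 ± 1.40 (SE, edgeR adjusted p = 0.000292), and the wild-type SD exceeded its mean. All 23 of its depleted-line counts lay in replicate 8, and without wild-type replicate 9 the log2 fold change was −7.53. The count at recovery 1 was 2420 without depleted replicate 17, 2002 without depleted replicate 12, 1925 without wild-type replicate 1 and 2430 with the compared groups fitted alone. With upper-quartile factors 1774 were higher and 2406 lower. The count at recovery 2 was 3468 without wild-type replicate 9, and its direction turned under upper-quartile scaling, with 2507 higher and 3054 lower (45.1% higher against 56.1%).

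Many of these genotype differences recurred over the conditions. In irrigated plants and at both recoveries, 1101 genes were higher and 775 were lower in the depleted line, where independent lists would share 55.5 and 36.9. The comparisons at the 3 conditions have no library in common. Over all genes, log2 fold changes of the irrigated comparison correlated across genes with r = 0.76 at recovery 1 and 0.63 at recovery 2, and genes are not independent replicates. Of 10145 genes called in any of the 3 conditions, 145 were higher in one and lower in another. The recurrent genes made up 8.23% to 10.6% of the genes tested on each of the 12 chromosomes. Their number, 1876, was 1226 without recovery 1 replicate 17 and 1204 without replicate 12 of the depleted line, and 1211 without wild-type recovery 1 replicate 1. Without replicate 16 it was 2273.

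In the wild type, no gene differed at the threshold between recovery from 1 drought and irrigation. The edgeR test called 0 genes, with a smallest adjusted p of 0.513, while 1380 genes had an unadjusted p under 0.05 and DESeq2 called 36. Solyc02g086850.2, which fell in the depleted line, stood at 54.9 ± 20.7 CPM in irrigated wild type and 2.19 ± 2.70 at recovery 1 (SD, n = 3), without being called there. In simulated data of this comparison a 2-fold change was recovered for 28% of genes and a 4-fold change for 68%, so some changes may have been missed. With the same number of libraries, the depleted line had 1713 calls at this recovery, but both genotypes had 0 with the compared groups fitted alone.

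After recovery from 2 droughts, 997 genes of the wild type differed from irrigation, 425 higher and 572 lower. Solyc07g052480.3 fell from 131 ± 85.1 to 2.54 ± 0.750 CPM (SD, n = 3), a log2 fold change of −5.69 ± 0.87 (SE, edgeR adjusted p = 0.00948). Solyc12g042830.2 rose from 1 count in irrigated wild type to 87.0 ± 146 CPM (SD, n = 3), a ratio of 8410 (95% interval 1510 to 332000), with 255 CPM in replicate 9 but 0.891 and 4.72 CPM in replicates 8 and 11. Replicate 9 decided the count, which was 0 without it, and both loci then lost their call, at an adjusted p of 0.0677 for each, with a log2 fold change of −5.59 for Solyc07g052480.3. The count was 573 without recovery replicate 8 and 432 without replicate 11, and 143 and 65 without irrigated replicates 6 and 7. Solyc12g042830.2 also lost its call without irrigated replicate 6 or 7, at adjusted p of 0.0515 and 0.0579. DESeq2 called 2342 genes, and the compared groups fitted alone gave 2033, in which Solyc12g042830.2 was not called (adjusted p = 0.0889). With upper-quartile factors 489 genes were higher and 484 lower, so the majority direction was not stable. With a log2 fold change of at least 1 the count was 593.

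The second recovery differed from the first in 62 genes of the wild type, 18 higher and 44 lower. Solyc05g045670.3 stood at 66.4 ± 39.5 CPM at recovery 1 and 1.01 ± 0.655 at recovery 2 (SD, n = 3), a log2 fold change of −6.07 ± 1.25 (SE, edgeR adjusted p = 0.0485). It lost its call without any 1 of the 6 libraries, with log2 fold changes of −5.63 to −6.58. The count of 62 was 5, 1 and 0 without recovery 1 replicates 1, 13 and 4, and 143, 0 and 0 without recovery 2 replicates 8, 11 and 9. The 143 were 71 higher and 72 lower, so the excess of lower genes was not stable. It was 11 without the low-count filter, 1 with these groups fitted alone and 621 with DESeq2, of which 262 were higher and 359 lower.

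In the depleted line, 1713 genes differed between recovery from 1 drought and irrigation, 576 higher and 1137 lower. Solyc02g071090.3 rose from 3.21 ± 0.696 to 48.6 ± 47.2 CPM (SD, n = 3), a log2 fold change of 3.92 ± 0.59 (SE, edgeR adjusted p = 0.00122), with 101 CPM in replicate 16, 34 in replicate 12 and 10.3 in replicate 17. Without replicate 16 the log2 fold change was 2.79. Solyc02g086850.2 fell from 16.1 ± 22.1 to 0.0511 ± 0.0459 CPM, a log2 fold change of −8.34 ± 1.75 (SE, edgeR adjusted p = 0.00749). Irrigated replicate 3 stood at 41.6 CPM and replicates 6 and 7 at 2.25 and 4.50, and without replicate 3 the log2 fold change was −6.09. Without recovery replicate 16 its log2 fold change was −7.67 and its adjusted p no longer lay under the threshold. Fitted with these 2 groups alone, 0 genes were called and both loci lost their call, at adjusted p = 0.0774 and 0.0738. The count was 728 without recovery replicate 16, of which 160 were higher, and 833 without replicate 12. It was 747 and 661 without irrigated replicates 6 and 7, 2756 with DESeq2 and 788 with a log2 fold change of at least 1.

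After 2 droughts, 2118 genes of the depleted line differed from irrigation, 887 higher and 1231 lower. Solyc02g084850.3 rose from 1.71 ± 2.00 to 192 ± 246 CPM (SD, n = 3), a log2 fold change of 6.82 ± 1.49 (SE, edgeR adjusted p = 0.00838). Replicate 8 stood at 475 CPM and replicates 13 and 11 at 35.4 and 65.7. The log2 fold change was 4.89 without replicate 8 and 8.41 without irrigated replicate 3, and the adjusted p reached 0.0499 without irrigated replicate 7. Solyc02g093890.1 rose from 0 counts to 2.20 ± 2.48 CPM, at least 45.8-fold, with 5.06 CPM in replicate 8 against 0.942 and 0.596 in replicates 13 and 11. Its adjusted p of 0.0128 missed the threshold without irrigated replicate 7 (0.0525), without recovery replicate 8 (0.0528) and with the compared groups fitted alone (0.0559). The count was 993 and 935 without irrigated replicates 6 and 7, and 1187, 1322 and 1230 without recovery replicates 13, 11 and 8. It was 991 with the compared groups fitted alone and 932 with a log2 fold change of at least 1. The 993 were 309 higher and 684 lower, and the 932 were 291 higher and 641 lower. Between the recoveries of the depleted line, edgeR called 0 genes, against 1749 at an unadjusted p under 0.05, 27 by DESeq2 and 3 without recovery 1 replicate 17.

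The genes called at both recoveries of the depleted line numbered 1110, 308 higher and 802 lower at both and none with opposite directions, where independent lists would share 25.1 and 68.7. They rest on the recovery 1 calls, which numbered 661 without irrigated replicate 7 and 0 with the compared groups fitted alone. The covariance of the log2 fold changes was 0.48, against 0.12 in simulations of unchanged groups, and part of the excess may come from the shared irrigated libraries. In the wild type, where recovery 1 had no calls, the covariance of the 2 recoveries was 0.30 against 0.11 simulated, with the same limit. Between genotypes, which share no library, the responses to recovery correlated across genes with r = 0.31 at recovery 1 and 0.26 at recovery 2. At recovery 2, 162 genes were called in both genotypes, of which 35 were higher and 61 lower in both and 66 moved in opposite directions, against 18.5, 34.6 and 50.6 for independent lists. These genes rest on the wild-type calls at recovery 2, which numbered 0 without replicate 9 and 65 without irrigated replicate 7.

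Genes called in the depleted line on recovery mostly moved against their genotype difference under irrigation. Of 1235 genes called at recovery 1 and in the irrigated genotype comparison, 1205 had opposite directions, against 301 for independent lists, and at recovery 2 the numbers were 1519 of 1546 against 368. The covariances were −0.39 and −0.44, against −0.12 simulated for both. Over all genes, r was −0.42 at both recoveries, against −0.51 simulated, and the share of genes with the same sign was 33.47% and 28.88%, against 33.07% and 33.29%. Of these 4 values, the share at recovery 2 alone went beyond its simulated value. Part of the opposite movement may come from the irrigated libraries of the depleted line that both comparisons use. No gene was changed in the simulations, so neither r nor the share can show how large that part is. With no library in common, 353 of 464 genes called in the depleted line at recovery 2 and between the genotypes at recovery 1 had opposite directions, against 208 for independent lists. For the recovery 1 response and the genotype comparison at recovery 2, 212 of 441 had opposite directions, against 237. All 4 overlaps rest on the calls of the depleted line at recoveries 1 and 2, which fell to 661 and 935 without irrigated replicate 7, and to 0 and 991 with the compared groups fitted alone.

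The difference between the genotypes in their response was tested as an interaction. It passed for 307 genes at recovery 1, 52 with a higher and 255 with a lower response in the depleted line, and for 1415 at recovery 2, 636 higher and 779 lower. At recovery 1, 295 of the 307 were called in the depleted line's response, and the wild type had no calls there that could overlap. At recovery 2, 766 were called in the depleted line alone, 66 in both with opposite directions, 314 in neither and the rest in the wild type alone. Of the 307 genes, 293 were also called between the irrigated genotypes, and of the 1415 genes, 1025 were. That comparison uses the same irrigated libraries as the interaction. The interaction uses the libraries of both responses, and the wild-type calls at recovery 2 rested on replicate 9. Solyc08g061590.3 rose from 23.4 ± 0.967 to 48.6 ± 1.10 and 63.8 ± 8.57 CPM in the depleted line, while wild-type levels were 68.7 ± 2.66, 56.6 ± 8.29 and 54.7 ± 5.28 CPM (SD, n = 3). Its interaction was 1.34 ± 0.17 at recovery 1 and 1.78 ± 0.17 at recovery 2 (log2, SE), with edgeR adjusted p of 0.00380 and 0.000125. Solyc06g068400.3 fell from 17.7 ± 4.33 to 4.93 ± 0.926 CPM in the depleted line at recovery 1, against 5.29 ± 0.338 and 7.27 ± 1.38 CPM in the wild type (SD, n = 3), an interaction of −2.30 ± 0.29 (log2, SE, edgeR adjusted p = 0.00380). With the 4 groups alone it was −2.25, with an adjusted p of 0.0595.

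The interaction counts moved with single libraries. At recovery 1 the count was 545, 96 and 19 without irrigated depleted replicates 3, 6 and 7, and 69 and 22 without recovery replicates 16 and 12 of that line. In the wild type it was 10 and 22 without recovery replicates 1 and 13, and 11 and 12 without irrigated replicates 6 and 7. It was 3 with the 4 groups fitted alone, 168 without the low-count filter and 769 with DESeq2, of which 256 were higher and 513 lower. At recovery 2 the count was 901 and 628 without irrigated depleted replicates 6 and 7, 743 and 858 without recovery replicates 13 and 11 of that line, 787 and 597 without wild-type recovery replicates 11 and 9, and 494 without irrigated wild-type replicate 7. DESeq2 called 2387.

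**Figure D3:**
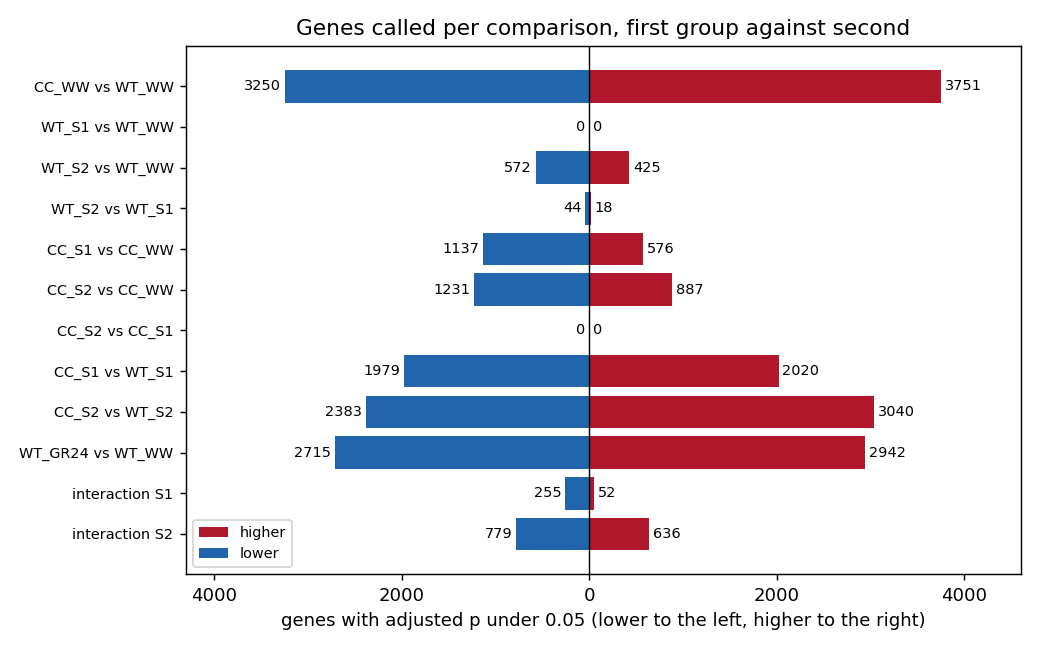
Genes called by edgeR at an adjusted p under 0.05 in each comparison, with higher calls to the right and lower calls to the left of 0 and the count at each bar (WT wild type, CC depleted line, WW irrigated, S1 and S2 recovery 1 and 2, GR24 spray; the interactions compare the recovery responses of the genotypes). Recovery 1 in the wild type and recovery 2 against recovery 1 in the depleted line have 0 calls.

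Wild-type leaves sampled 24 h after the GR24 spray differed from irrigated wild type in 5657 genes, 2942 higher and 2715 lower. With upper-quartile factors the numbers were 2815 and 2799, and with DESeq2 size factors 2785 and 2837, so the majority direction was not stable. Solyc12g087940.2 rose from 0 counts to 23.9 ± 20.5 CPM (SD, n = 3), at least 788-fold, at 36.5 and 35 CPM in replicates 9 and 11 and 0.168 in replicate 8. Solyc01g102910.3 fell from 11.3 ± 13.8 CPM to 1 count, a ratio of 1000 (95% interval 180 to 39700), and its irrigated libraries stood at 0.379, 6.72 and 26.8 CPM in replicates 6, 7 and 14. The interval covers counting error and not this spread. The 10 most abundant genes took 6.70 ± 1.37% of the counts in sprayed leaves and 9.53 ± 0.73% in irrigated ones (SD, n = 3). Wild type at recoveries 1 and 2 stood between them, at 7.92 ± 0.26% and 8.16 ± 0.47% (SD, n = 3). These shares were not tested. The count of changed genes was 3617 without irrigated replicate 7, 3458 with the 2 groups fitted alone and 2937 with a log2 fold change of at least 1.

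Many genes that differed between the depleted line and the wild type differed in the same direction between sprayed and irrigated wild type. Neither comparison separates the hormone level from other differences of the line or of the spray. Of 1401 genes higher in the depleted line at both recoveries, 547 were also higher after the spray and 39 lower, where independent lists would share 202 and 187. Of 1067 genes lower at both recoveries, 321 were also lower after the spray and 45 higher, against 142 and 154. These comparisons share no library with the spray comparison. The genes that moved in opposite directions, 84 in all, were 54 without the low-count filter, 147 with DESeq2 and 20 with the compared groups fitted alone. They were 34 and 35 without depleted recovery 1 replicates 17 and 12, 32 and 41 without wild-type recovery 1 replicates 1 and 13, 55 and 130 without sprayed replicates 8 and 9, and 34 and 36 without irrigated wild-type replicates 6 and 7. The genes that moved in the same direction, 868 in all, were 492 with the compared groups fitted alone.

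Under irrigation, where both comparisons use the same control libraries, 3028 genes were called between the genotypes and for the spray, and 2905 of them moved in the same direction. Both were higher for 1695 genes and both lower for 1210, against 542 and 433 for independent lists. The covariance of the log2 fold changes was 0.67, against 0.11 simulated, while r was 0.50 both observed and simulated. Part of the covariance excess may come from the shared controls. No gene was changed in the simulations, so the equal r cannot show how large that part is. With recovery 1 wild type as the control of the spray, and so no library in common, the covariance was still 0.57. Between the spray and the genotype comparison at recovery 1, with no shared library, the correlation across genes was 0.36. In that pair 1430 of 1571 genes moved in the same direction. For the genotype comparison at recovery 2 the correlation was 0.22, and 1278 of 1688 did.

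**Figure D4:**
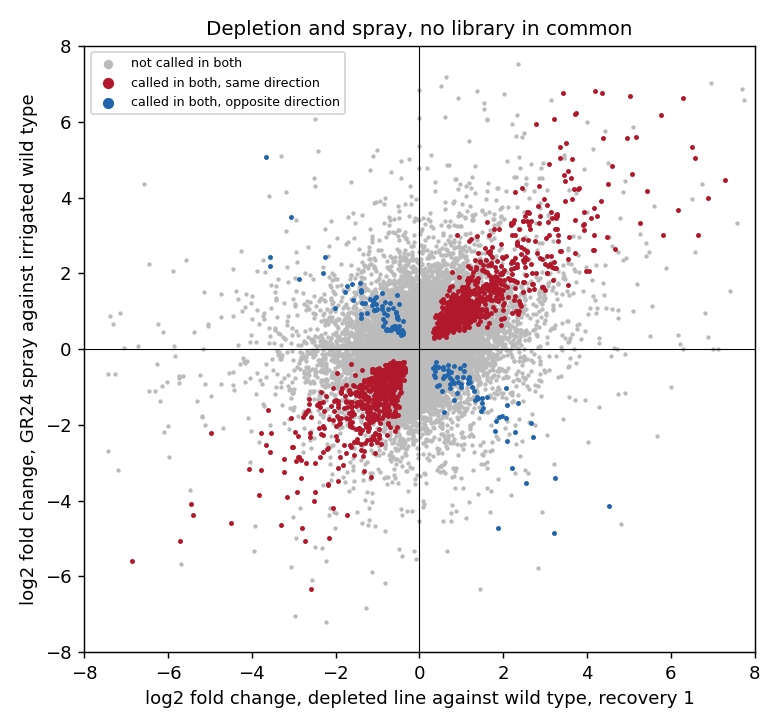
Log2 fold change of each gene in the depleted line against wild type at recovery 1 (horizontal) and after the GR24 spray against irrigated wild type (vertical), comparisons with no library in common; 24 genes lie outside the axes. Of the 1571 genes called in both, 1430 moved in the same direction (red) and 141 in opposite directions (blue).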

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

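The tests of shared control libraries by recovery groups, of library 16 and of the silencing construct were chosen only after the result was seen. The tests with another control, without single spray libraries and with other divisions of the libraries were written down before their results were known. No group held 4 or more libraries, so no library was tested for standing apart from its group by its range.

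The responses of the genotypes to recovery differed by the interaction test in 307 genes at recovery 1 and 1415 at recovery 2. IDs of smallest p were taken separately for higher and lower differences, 2 of each. At recovery 1 they were Solyc08g061590.3 (log2 difference 1.34), Solyc08g005450.2 (1.22), Solyc06g068400.3 (−2.30) and Solyc07g064350.2 (−1.79). The last 3 lost their call with the 4 groups fitted alone, at adjusted p of 0.0595, 0.0595 and 0.0667. At recovery 2 they were Solyc08g061590.3 (1.78), Solyc08g005450.2 (1.60), Solyc03g116380.3 (−2.43) and Solyc03g118680.3 (−1.82). Under irrigation the depleted line lay below the wild type for the first 2 IDs, by −1.56 and −1.45 on the log2 scale, and above it for the other 4, by 1.75, 2.07, 1.25 and 1.26.

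For each interaction, 100 divisions of the 12 libraries were compared, the real one included. At recovery 1, 6 of the 100 gave as many genes as the real 307, with a highest other of 6304, so chance was not excluded. At recovery 2, 4 of the 100 gave as many as the real 1415, with a highest other of 6261, a share under 0.05. Divisions with several times the real count point to a structure of the libraries, and in both cases the highest other largely followed the genotypes. The divisions move libraries across genotypes, so the genotype difference enters them, and the shares of the 2 recoveries lie close together. The share at recovery 2 therefore does not by itself exclude chance.

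For each comparison of 2 groups the 6 libraries divide in 10 ways, too few for a share under 0.05. The real division gave 7001 genes between irrigated genotypes, 3999 at recovery 1, 5423 at recovery 2, 5657 for the spray, 997 and 62 for recovery 2 in the wild type against irrigation and recovery 1, and 2118 for recovery 2 in the depleted line. In each of these the highest other was 0 and 1 division, the real one, reached the count. For recovery 1 in the depleted line the real value was 1713 and the highest other 13. For recovery 1 in the wild type and for the 2 recoveries of the depleted line, all 10 divisions gave 0.

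Many genes differed in the same direction between sprayed and irrigated wild type and between the depleted line and the wild type, although the spray adds a strigolactone analogue. Shared control libraries as the whole cause are argued against by genes called for the spray and, in 1 direction, at both recoveries. Of these 952 genes, 91.2% had the same direction with no library in common. With each recovery taken singly, 1430 of 1571 genes had the direction of the spray at recovery 1. At recovery 2 it was 1278 of 1688 (75.7%). With recovery 1 wild type as the control of the spray, the covariance was 0.57 (0.53 to 0.63 without each library of that control). The limit set was 0.1. This argues against irrigated wild-type libraries that stand apart as the whole cause. On the second component those libraries did lie above all others, opposite the sprayed ones. Recovery 1 wild type, with 0 calls against them, may share part of that deviation. Recovery 2 wild type was not tried as the control. A single spray library is argued against by a lowest same-direction share of 85.4% when each was left out. A candidate explanation that stays open is a response of the leaf to a hormone level away from its usual one, or feedback on the hormone pathway. Other differences of the line stay open as well. Effects of the solvent or of sampling time were not tested, since no spray without GR24 was analysed here and the time labels of the sprayed and irrigated groups differ.

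Depleted library 16 of recovery 1 lay at −11.1 on the first component, nearest the wild type of its genotype. Wild-type RNA mixed into it is argued against by Solyc07g052790.2, which had 1 count there, at most 0.622% of its mean wild-type level by the 95% counting limit. A wild-type library with a wrong label is argued against by the loci read in the depleted line, the lowest of which stood at 10 CPM in it, against at most 0.432 in any wild-type library. A difference between plants in how far they had recovered may remain, and no test bears on it.

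Solyc01g090660.3 had 43768 counts over the 9 depleted libraries and 0 over the 12 wild-type ones. A candidate explanation is that its reads stem from the silencing construct, which would carry sequence of the silenced gene. The ID was in the list of strigolactone loci written before the data were examined, its number places it on chromosome 1, and CCD7 lies on chromosome 1 in the RefSeq table. That table matched none of the IDs and no reads were used here, so the construct, a transcript of the locus itself and another gene cannot be told apart.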

How the results depend on the processing

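Alternatives for counts over several comparisons were chosen after seeing the data, all others before. Of 176 alternative counts of single comparisons, 109 lay within 1.5 times the reported count. Of 555 values of single IDs under alternatives, 483 kept their direction and call, 72 kept their direction and lost their call, and 0 reversed. IDs left without an adjusted p by an alternative are not among the 555. DESeq2 gave 37 values, and the filter of 1 CPM and the compared groups alone gave 39 each. Each change of scaling factors gave 40. No scaling moved the median of all genes by over 0.09 on the log2 scale. The depth of 19267602 counts in the shallowest library set a floor of 0.156 CPM there at 3 counts, and the planned tests of gene lists and of the silenced gene were not run.

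Without the low-count filter, 11 genes differed between the wild-type recoveries, 168 in the interaction at recovery 1, and 54 moved against the spray. DESeq2 called 36 genes for recovery 1 and 2342 for recovery 2 in the wild type, 621 between them, 2756 for recovery 1 and 27 between recoveries in the depleted line, 769 and 2387 for the interactions, and 147 that moved against the spray. The cause was not tested. A fit of the compared groups alone has fewer libraries and takes the spread from those groups only. In the wild type its counts were 2033 for recovery 2, above the reported 997, and 1 between recoveries. In the depleted line they were 0 and 991 for recoveries 1 and 2. They were 2430 between genotypes at recovery 1, 3458 for the spray and 3 for the interaction at recovery 1. Why these counts moved was not tested. The genotype difference at both recoveries then shared 492 genes with the spray in the same direction and 20 in the opposite one. A log2 fold change of at least 1, which keeps fewer genes by construction, left 3734, 2236 and 3180 between genotypes under irrigation and at recoveries 1 and 2, 593 for recovery 2 in the wild type, 788 and 932 for the recoveries of the depleted line, and 2937 for the spray.

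Leaving out 1 library at a time gave 4822 to 6566 genes between irrigated genotypes, 1925 to 4562 at recovery 1 and 3468 to 4817 at recovery 2. In the wild type it gave 0 to 0 for recovery 1, 0 to 989 for recovery 2 and 0 to 143 between them. In the depleted line it gave 661 to 2526, 935 to 2673 and 0 to 3. For the spray it gave 3617 to 5290, and for the interactions 10 to 545 and 494 to 1947. Genes that differed between genotypes in all 3 conditions ranged from 1204 to 2273, and those shared with the spray from 598 to 1093 in the same direction and from 32 to 130 in the opposite one.

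Same-numbered libraries of the genotypes showed no shared deviation. Their deviations from the group means correlated at 0.06 and −0.05 for irrigated replicates 6 and 7, and at −0.01 and 0.02 for recovery 2 replicates 8 and 11. Batches that do not follow these numbers were not tested. With the replicate number as a block, 5909 genes differed between irrigated genotypes on libraries 6 and 7, against 6974 without the block. At recovery 2, on libraries 8 and 11, they were 1384 with the replicate block and 1937 without it. In limma over all libraries, the block gave 6456 and 4923, against 6576 and 5049 without it.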

Other observations

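The test of neighbouring genes below was written down before its result was known, and the other values were looked up after the data were seen. Genes of the wild type called both for recovery from 2 droughts and for the spray mostly moved the same way. Of 507 genes called in both, 223 were higher and 249 lower in both and 35 had opposite directions, against 61.4, 76.2 and 139 for independent lists. Both comparisons use the irrigated wild-type libraries, and the covariance was 0.37 against 0.11 in simulations of unchanged groups. Over all genes, r was 0.38 against 0.50 simulated, and 62.92% of genes had the same sign against 66.68% simulated. Part of the overlap may come from the shared controls. The simulations cannot show how much of it does, since no gene was changed in them. The count of genes called for recovery 2 was 0 without wild-type recovery 2 replicate 9.

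Wild-type Solyc01g103920.3 stood at 17.4 ± 6.60 CPM under irrigation, 87.5 ± 70.8 at recovery 1 (SD, n = 3) and between 93 and 605 in the 3 libraries of recovery 2. It stood at 0.0790 ± 0.0983, 1.28 ± 1.11 and 1.14 ± 1.22 CPM in the depleted line (SD, n = 3). Solyc02g084850.3 stood at 1540 ± 2270 CPM in sprayed leaves and 2.47 ± 1.08 in irrigated wild type (SD, n = 3), with 4160 CPM in sprayed replicate 8 against 197 and 251 in replicates 9 and 11. Both IDs were singled out here after their values were seen.

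Of the 67 ENSRNA IDs tested, 10 were higher and 3 lower in the depleted line under irrigation. The numbers were 2 and 3 at recovery 1 and 2 and 6 at recovery 2, so the majority direction of the calls changed. Whether single IDs kept their direction was not examined. After the spray 5 were higher and 5 lower.

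A hypothesis was that the 2 lines differ in chromosome segments, so that called genes would lie next to each other more often than for the spray. Among 1875 genes that differed between genotypes in all 3 conditions, 137 neighbouring pairs had the same direction, against 89.0 expected from 1000 permutations within chromosomes, a ratio of 1.54. As many genes of smallest p for the spray gave 149 pairs, a ratio of 1.69, and all 5646 called spray genes gave a ratio of 1.30. The quotient against the matched spray genes was 0.91, below the 1.2 set as the limit. Against all called spray genes, a larger set with smaller changes, it was 1.19, just under that limit. The test counts only neighbours with the same direction, while a segment could hold genes of both directions. Many of the genes were also called for the spray, so the 2 sets are not independent. The test therefore cannot decide whether segments contribute. Single segments, such as Solyc06g060640.1 and the ID next to it, may still differ.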
